A study of Mus musculus with 23 samples.

How the data were processed

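RNA from sorted male germ cells was hybridised to Affymetrix mouse arrays, and the 23 arrays were grouped as the labels give them. The deposited values are intensity, summarised per probe set with GCRMA by the authors; the labels give no version or settings for it. The values ran from 1.48 to 107451 and were therefore read as linear, not logarithmic, and their medians differed between arrays. They were analysed as log2(value + 1). No scanner output was used, and every column of deposited values was used.

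The table held 45037 probe sets. The platform table gave exactly 1 gene symbol to 34945 of them, several to 932, and did not list 9160; the latter groups were left out. Symbols and chromosomes came from the RefSeq annotation of GRCm38.p6, joined by Entrez identifier for 34741 probe sets; the rest kept the symbol of the platform table and no chromosome. This gave 18193 genes. Each of the 9010 genes with more than 1 probe set was represented by the probe set with the highest mean over the arrays of the fit. Genes were kept where log2 was at least 4 in at least 2 arrays, which left 13087 genes over the 20 wild-type arrays and 12015 over the 13 arrays of the 3 fractions with Spo11-/- samples.

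Changes were tested with limma 3.58.1 in R 4.3.3. A mean per fraction was fitted over the 20 wild-type arrays, and adjacent fractions with at least 2 arrays were compared, so that the spread came from all wild-type fractions with replicates. The Spo11-/- comparison was fitted with fraction and genotype as additive terms; with 1 Spo11-/- array per fraction it tested the shift shared by the 3 fractions, and it took the 3 arrays as independent although they may hold cells of the same mice. A gene was said to rise or fall where its Benjamini-Hochberg adjusted p over all genes tested was below 0.05 and its absolute log2 change at least 1. Within single fractions, with 1 Spo11-/- array each, genes at least log2 2 beyond every wild-type array of the fraction were counted without a test, and each wild-type array was set against the others of its fraction in the same way. As an alternative, each fraction and the interaction of fraction and genotype were tested in limma with the spread of the wild-type arrays alone, which assumes that the lone Spo11-/- array varies like them.

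The 23 gene lists held 404 entries, of which 366 were on the array. They covered stages (spermatogonial, meiotic entry, late prophase and spermatid genes), processes (DNA replication, double-strand break formation, the chromosome axis and synaptonemal complex, strand exchange and crossover, sex chromosome silencing, the piRNA pathway, p53 targets), chromatin (histone acetyltransferases, histone deacetylases, bromodomain readers, H3K4 methylation writers and erasers, H3K9 and H3K36 methylation enzymes, histone variants) and other cell types (Sertoli, Leydig, peritubular and stromal, macrophage and leukocyte, endothelial and red blood cell markers). Lists with at least 3 measured members were tested with limma's camera at a preset correlation of 0.01, again with the correlation estimated, and with fry, with Benjamini-Hochberg adjustment over 132 tests; red blood cell markers had too few members. Counts of members were also adjusted over the list alone. The lists, the tests, the filters, the rule for named genes and most alternatives were fixed before the data were examined; lists of T cell and B cell markers, 3 alternatives, and the list tests without each array were added later.

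The rule named, in each comparison, the 8 largest fitted rises and falls among genes past the test whose 2 groups of arrays did not overlap, leaving out predicted gene names, and up to 4 members of each list past the test, or up to 2 given as values where none passed. Spo11, Prdm9, Dmc1, Sycp3, Stra8, Brdt, Kat2b, Ep300, Crebbp and Hat1 were always looked at. The level of X-linked genes was the median log2 of X-linked genes minus that of autosomal genes in each array, compared between groups of arrays with two-sided exact permutation tests; numbers of X-linked and autosomal genes past the test were compared with Fisher's exact test, Benjamini-Hochberg adjusted over 10 tests.

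Replicate numbers in the labels of 18 wild-type arrays are not said to mark a shared animal or day. Over the 26200 probe sets past the filter, the deviations of same-numbered arrays from their group means correlated at 0.58, 0.53 and 0.19 between spermatogonia and pre-leptotene, and at 0.61, 0.32 and 0.45 between pre-leptotene and leptotene/zygotene. All of these lay above 0.1, so fits with the replicate number as a block are given beside both results; over the 13087 genes tested, the lowest of the 6 correlations was 0.08. The other comparisons had 2 pairs each.

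Alternatives covered the filter, the choice of probe set, quantile normalization and median centring, eBayes with trend and robust settings, array weights, the fold minimum, leaving out each array, a fit on the arrays of the 2 fractions alone, the replicate block, all 4 pachytene arrays as 1 group, and a model without the fraction term. The procedure was also tested on simulated data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.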

Results

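Gene expression was measured on 23 Affymetrix mouse arrays of male germ cells that had been sorted by flow cytometry after staining with Hoechst, a dye that binds DNA. The 20 wild-type arrays came from mice aged 10 to 16 weeks and covered spermatogonia (4 arrays), pre-leptotene (3) and leptotene/zygotene (3) spermatocytes, early (1), mid (2) and late (1) pachytene and diplotene (2) spermatocytes, and round spermatids (4). The other 3 arrays held spermatogonia, pre-leptotene and leptotene/zygotene cells of Spo11-/- mice, which lack the enzyme that makes meiotic double-strand breaks, with 1 array per fraction. Cells for the Spo11-/- arrays were pooled from 2 collections. Whether the 3 arrays share mice is not stated, and the fit took them as independent. The labels call the wild-type arrays biological replicates, so the p-values measure the spread between arrays, and the number of arrays limits the precision. Median intensity per array ran from 10.63 to 12.56, and between 44.2% and 47.3% of probe sets had a log2 of at least 4. The 10 brightest probe sets held between 2.24% and 2.61% of the summed intensity. Levels are given as mean log2 intensity ± SD over arrays and changes as log2 ± SE. A group with every array below log2 4, the level of the filter, was taken as not above background. A change against it is given as a bound (at least or at most), the mean of the other group minus 4. Where a single count is given for a gene list, the count adjusted over the list alone was the same. Genes of histone acetylation were followed through all fractions because the title of the series concerns acetylated histones at sites of meiotic recombination.

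**Figure D1:**
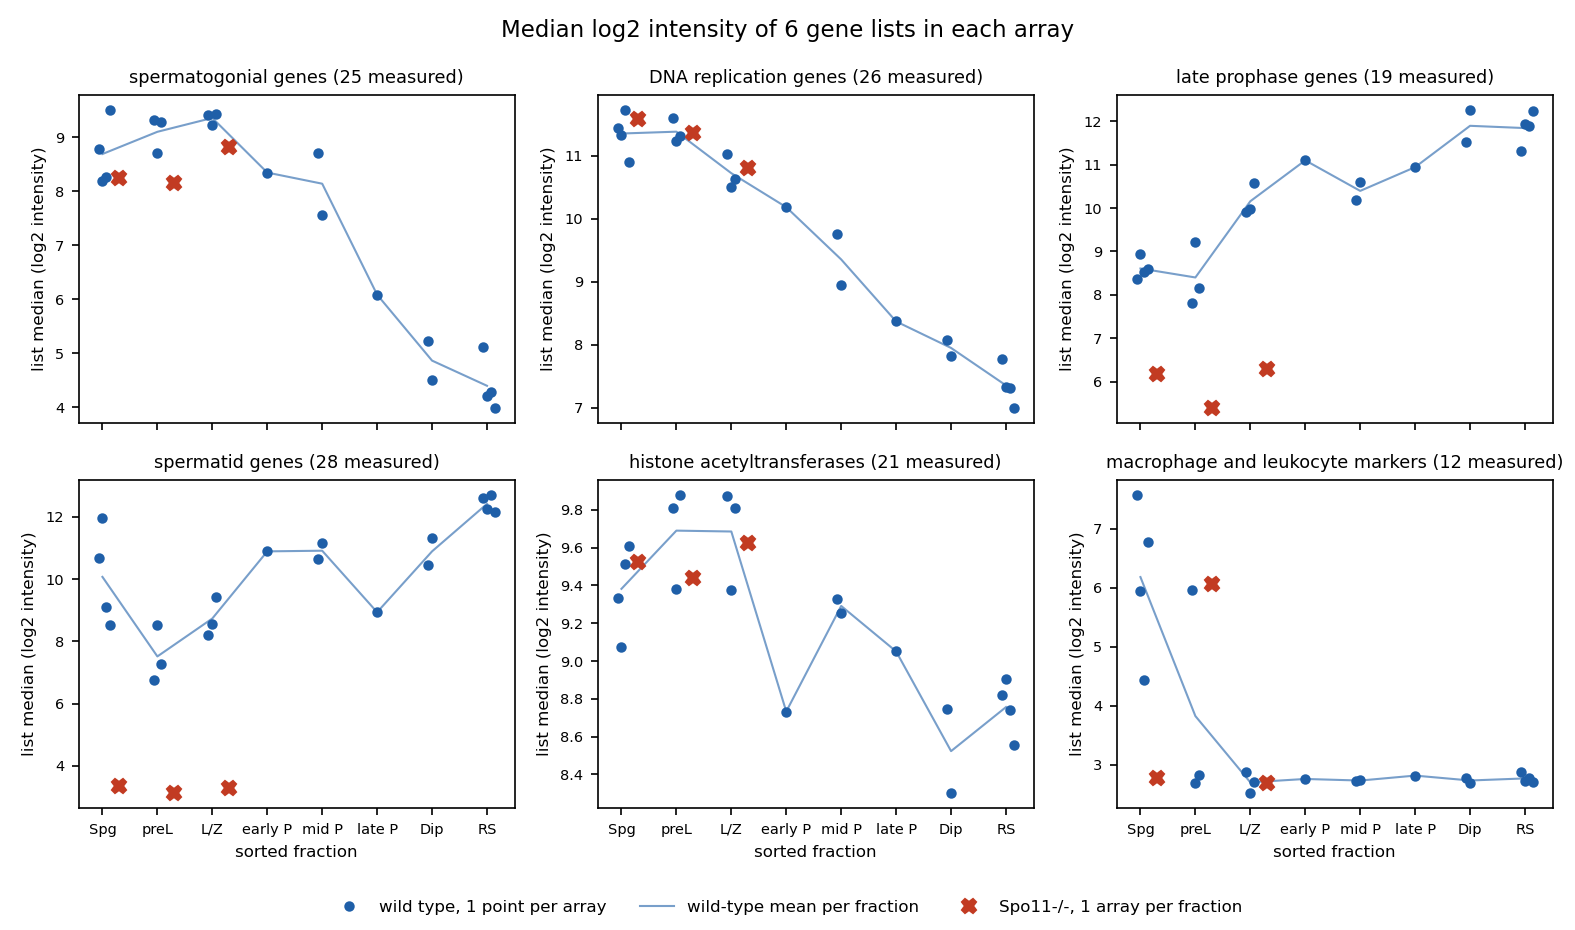
Median log2 intensity of 6 gene lists (vertical axis) in each array, by fraction (horizontal axis); points are wild-type arrays, the line joins their means, and red crosses are the Spo11-/- arrays. The spermatid genes lay between 6.74 and 11.97 in the wild-type spermatogonia and pre-leptotene arrays and between 3.12 and 3.35 in the Spo11-/- arrays.

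Between spermatogonia and pre-leptotene spermatocytes, the cells that replicate DNA before meiosis, some genes of spermatids and of other cell types fell. Of 28 spermatid genes, 7 fell and 21 did not pass the test, and 16 fell when adjusted over the list alone. Tnp2, which encodes a protein that replaces histones in sperm, went from 13.81 ± 1.19 in 4 spermatogonia arrays to 11.17 ± 0.38 in 3 pre-leptotene arrays (-2.64 ± 0.47, adjusted p = 0.0311). The kinase genes Tssk2 (-2.94 ± 0.64) and Tssk3 (-2.86 ± 0.59) and the sperm tail gene Akap4 (-2.62 ± 0.56) fell as well. Of 12 macrophage and leukocyte markers 2 fell (6 when adjusted over the list alone): the lysozyme gene Lyz2 (4.20 ± 1.51 against 9.01 ± 1.07, -4.80 ± 0.58, adjusted p = 0.00127) and Ptprc, the common leukocyte antigen (-4.06 ± 0.52). Of 10 peritubular and stromal markers 3 fell (6 when adjusted over the list alone), all of extracellular matrix: Dcn (-4.23 ± 1.03), Col3a1 (-3.37 ± 0.70) and Col1a2 (-3.23 ± 0.70). Among the named falls were also S100a4 (-4.44 ± 0.47), Lyz1 (-4.22 ± 0.69) and the chemokine gene Ccl5 (at most -1.90), and of 19 late prophase genes 1 fell, the glycolysis gene Pgk2 (-2.59 ± 0.58); adjusted over the list alone 2 fell and 1 rose. The 8 genes that rose included Lad1 (5.84 ± 0.63 against 3.32 ± 0.20, at least 1.84, adjusted p = 0.000773), Plch2 (1.87 ± 0.37), the cyclin gene Ccnf (1.26 ± 0.26) and Sgo2a, which protects cohesion in meiosis (1.06 ± 0.23).

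In 15 germ cell and chromatin lists, with 241 genes, limma put 0 genes past the test in this comparison, and 14 had an unadjusted p below 0.05. With the replicate number as a block 1 replication gene, 1 acetyltransferase gene and 3 histone variants of these lists were lower. Adjusted over the list alone, 1 of 21 acetyltransferase genes fell, and of 13 histone variants 3 fell and 1 rose. These lists held spermatogonial, meiotic entry, DNA replication, double-strand break, axis, strand exchange and piRNA genes and those of chromatin. The median change was 0.19 for spermatogonial, 0.12 for meiotic entry and -0.10 for DNA replication genes. None of these passed in limma's camera test (adjusted p = 0.248, 0.340 and 0.541). With so few arrays this does not show that the lists are alike in the 2 fractions. Changes were 0.23 ± 0.79 for Stra8, a switch gene of meiotic entry, 0.02 ± 0.67 for Spo11, 0.15 ± 0.21 for Sycp3, -0.07 ± 0.25 for Hat1, 0.31 ± 0.26 for Crebbp and 0.21 ± 0.23 for Ep300. The 24 markers of the 4 other cell type lists gave 0 genes past limma's test, 1 of them with an unadjusted p below 0.05. As lists, the spermatid genes (median -1.56, adjusted camera p = 8.21e-19), stromal markers (-2.06, 2.65e-08) and leukocyte markers (-1.90, 1.60e-07) were lower than other genes, with adjusted p = 0.803 with an estimated correlation for each. Arrays stood apart within the fractions. The spermatid medians were 10.69, 11.97, 9.11 and 8.53 in spermatogonia arrays 1 to 4 and 6.74, 8.54 and 7.27 in the pre-leptotene arrays, the stromal median was 9.61 in spermatogonia array 4 and 5.90 to 7.63 in the others, and the leukocyte median was 5.97 in pre-leptotene array 1 and 2.69 and 2.83 in the others. These 3 calls stayed past the threshold without any 1 of the 7 arrays, but the medians moved. They ran from -2.28 to -1.31 for spermatid genes, -2.47 to -1.29 for stromal and -3.14 to -1.31 for leukocyte markers. Bromodomain readers (median 0.21, adjusted camera p = 0.0266) and H3K4 methylation genes (0.16, 0.0154) were higher than other genes, again with adjusted p = 0.803 with an estimated correlation. Without each of the 7 arrays in turn their medians ran from 0.05 to 0.27 and from 0.09 to 0.34. The bromodomain call ended without spermatogonia array 1 or 2 or pre-leptotene array 2 or 3 (limma's camera test, adjusted p = 0.0618, 0.110, 0.0576 and 0.0519) and the H3K4 call without spermatogonia array 2 (0.0919). With the replicate number as a block piRNA genes passed in limma's camera test too (median 0.12, adjusted p = 0.0343, against 0.145).

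In all, 223 of 13087 genes passed, 8 higher and 215 lower, and 203 of them had arrays that did not overlap. Over all genes 8.92% did not overlap, where chance gives 5.71%. With the replicate number as a block 625 genes passed (33 higher, 592 lower) and 16 spermatid, 3 leukocyte and 2 stromal genes fell, while a limma fit on the arrays of these 2 fractions alone gave 0, with 1222 at an unadjusted p below 0.05. Quantile normalization left 10 higher and 17 lower (37.0% higher, against 3.59%) and median centring 9 and 28 (24.3%), with the median of all genes moving from -0.01 to 0.11 and 0.16; 37 genes passed among those not higher in a later fraction. The count was 23, 56, 428 and 596 without spermatogonia arrays 1, 2, 3 and 4 in turn, 38 and 8 without pre-leptotene arrays 1 and 3, and 39 without spermatogonia arrays 1 and 2 together.

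From pre-leptotene to leptotene/zygotene, when chromosomes condense and breaks are made, some genes of late prophase and of spermatids rose. Of 19 late prophase genes 7 rose and 12 did not pass, with 10 when adjusted over the list alone. Ldhc, the lactate dehydrogenase of germ cells, went from 10.70 ± 0.73 to 13.37 ± 0.73 (3 arrays each, 2.67 ± 0.44, adjusted p = 0.00901), and the sperm surface gene Adam2 (3.99 ± 0.85), Spata16 (2.73 ± 0.67) and the chaperone gene Clgn (2.37 ± 0.58) rose too. Of 28 spermatid genes 2 rose, Acr, the protease of the acrosome (3.33 ± 0.68), and the transcription factor gene Rfx2 (2.38 ± 0.51), and 11 rose when adjusted over the list alone. Of 17 piRNA pathway genes, which silence transposons, 2 rose, also when adjusted over the list alone: Piwil1 (7.74 ± 0.36 to 10.06 ± 0.29, 2.33 ± 0.31, adjusted p = 0.00466) and Mybl1, its transcription factor (1.38 ± 0.36). Cers3, a ceramide synthase gene (4.34 ± 0.84, adjusted p = 0.0147), Cabcoco1 (3.93 ± 0.75), Glipr1l2 (3.73 ± 0.62), Zmynd10 (3.69 ± 0.75) and Cfap65 (3.55 ± 0.57) were among the largest rises, the latter pair being genes of cilia. The spermatogonial gene Id4 (2.22 ± 0.58), the H3K9 demethylase gene Kdm4d (2.71 ± 0.51) and the Leydig cell marker Cyp17a1, a steroid enzyme gene (3.41 ± 0.69), were the single members of their lists that rose. The 10 falls included E2f2, a regulator of the cell cycle (-2.61 ± 0.46, adjusted p = 0.0106), Megf11 (at most -1.05), Zfp398 (-1.74 ± 0.36) and the linker histone gene H1f10 (-1.38 ± 0.32).

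In 11 germ cell and chromatin lists, with 170 genes, limma put 0 genes past the test between these fractions, and 14 had an unadjusted p below 0.05; for 40 markers in 5 lists of other cell types the numbers were 0 and 1. With the replicate number as a block, 1 break formation gene, 1 bromodomain gene and 1 H3K4 gene were higher. Spo11 was at 8.37 ± 0.83 in leptotene/zygotene and 5.96 ± 1.23 in pre-leptotene (2.41 ± 0.72, adjusted p = 0.0844; 1 of 6 break formation genes rose when adjusted over the list alone), Sycp3, a protein of the chromosome axis, at 0.66 ± 0.22, the testis bromodomain gene Brdt at 1.07 ± 0.37 and the strand exchange gene Dmc1 at -0.42 ± 0.36. As lists, late prophase genes (median 1.31, adjusted camera p = 1.79e-07), spermatid genes (0.91, 0.000875), piRNA genes (0.52, 0.000875) and Leydig cell markers (0.91, or 0.27 with genes below log2 4 at their bounds, 0.0256) were higher than other genes, with adjusted p = 0.803 with an estimated correlation. DNA replication genes (-0.33, 0.00156) and leukocyte markers (-1.15, or -0.02 with the bounds, 0.000563) were lower, again with adjusted p = 0.803 with an estimated correlation. The leukocyte call rested on pre-leptotene array 1, with a median of 5.97 against 2.69 and 2.83 in the other 2 and 2.52 to 2.89 in leptotene/zygotene. Without that array the change was 0.01 (limma's camera test, adjusted p = 0.450), and the calls of spermatid genes (0.68, 0.0536) and Leydig cell markers (0.84, 0.105) ended too. The Leydig call also ended without leptotene/zygotene array 1 (0.92, 0.0750).

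In all, 407 of 13087 genes passed, 397 higher and 10 lower; 404 did not overlap, and over all genes 20.3% did not, against 10% by chance. With the replicate number as a block 630 passed (607 higher, 23 lower), with 9 late prophase and 9 spermatid genes higher and 2 histone variants lower, and a limma fit on the arrays of these 2 fractions alone gave 0 (2021 at an unadjusted p below 0.05). Among the 5880 genes not higher in a later fraction limma gave 0, with 282 at an unadjusted p below 0.05. In the Spo11-/- arrays the spermatid medians were 3.12 in pre-leptotene and 3.27 in leptotene/zygotene. Wild-type leptotene/zygotene arrays had 8.21, 8.56 and 9.43. The late prophase medians were 5.40 and 6.30 in those Spo11-/- arrays, against 9.91, 9.99 and 10.57 in wild-type leptotene/zygotene. Of 419 X-linked genes 0 rose at this step, against 396 of 12586 autosomal genes (Fisher's exact adjusted p = 5.09e-06). Of the falls, 0 were X-linked and 10 autosomal. Whether RNA of later germ cells contributed to the wild-type rise was not tested. Quantile normalization gave 208 higher and 24 lower and median centring 184 and 12, with the median of all genes at -0.10 and -0.16. Without pre-leptotene array 1 or 3 the count was 25 or 64, and without leptotene/zygotene array 1, 2 or 3 it was 623, 248 or 33.

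By mid-pachytene, when homologous chromosomes are fully paired, 11 of 28 spermatid genes and 9 of 19 late prophase genes had risen, while 11 of 26 DNA replication genes had fallen. Of 28 spermatid genes 11 rose and 17 did not pass (12 when adjusted over the list alone), among them Acr (3.43 ± 0.76), Sun5, which joins the sperm head and tail (2.90 ± 0.95), and Rfx2 (2.69 ± 0.57). Of 19 late prophase genes 9 rose, with Adam2 at 2.89 ± 0.95 and Clgn at 2.59 ± 0.65, and 2 fell. Of 17 piRNA genes 4 rose, Piwil1 (10.06 ± 0.29 in 3 arrays to 13.61 ± 0.14 in 2, 3.54 ± 0.35, adjusted p = 2.14e-05), Tdrd5 (2.11 ± 0.46), Mybl1 (2.10 ± 0.40) and Pld6 (2.08 ± 0.30). Of 26 DNA replication genes 11 fell and 15 did not pass (12 when adjusted over the list alone), such as Rrm2 (-2.31 ± 0.34), Cdc6 (-2.14 ± 0.29) and Mcm2 (-2.09 ± 0.66). Of 25 spermatogonial genes 9 fell, with the receptor gene Kit at -2.70 ± 0.52, and 1 rose, Id4 (2.66 ± 0.65). Of 10 meiotic entry genes 2 fell, Prdm9, the H3K4 methyltransferase that places breaks (at most -0.67), and Scml2 (-2.05 ± 0.46).

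The genes of recombination went both ways between leptotene/zygotene and mid-pachytene. Of 6 break formation genes Prdm9, Mei1 (-2.10 ± 0.37) and Mei4 (-1.58 ± 0.44) fell and Spo11 rose (8.37 ± 0.83 to 11.78 ± 1.39, 3.41 ± 0.80, adjusted p = 0.00494); adjusted over the list alone, 4 fell and 2 rose. The call on Spo11 ended without mid-pachytene array 2. Of 18 strand exchange and crossover genes 6 fell, among them Tex11 (-2.97 ± 0.69), Dmc1 (6.60 ± 0.41 against 8.95 ± 0.35, -2.36 ± 0.40, adjusted p = 0.000626) and Brca1 (-1.54 ± 0.38), and 5 rose, such as the crossover genes Msh4 (1.90 ± 0.59) and Mlh3 (1.70 ± 0.27). Of 13 axis genes Sycp2 (1.59 ± 0.35) and Syce1 (1.13 ± 0.36) rose and the others did not pass. Of 12 genes of sex chromosome silencing 3 rose, including Mdc1 (2.01 ± 0.38) and H2ax (1.09 ± 0.27), which spread the silencing mark, and 2 fell.

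Histone acetyltransferase genes fell in larger number than they rose at this step. Of 21 measured, 9 fell, 2 rose and 10 did not pass. Crebbp went from 12.42 ± 0.21 to 10.84 ± 0.41 (-1.58 ± 0.31, adjusted p = 0.00166), and its relative Ep300 (-1.45 ± 0.28), Taf1 (-2.01 ± 0.59), Ncoa3 (-1.89 ± 0.37), Naa60 (-1.71 ± 0.35) and Hat1, which acetylates new histone H4 (-1.25 ± 0.30), fell as well. Of 16 deacetylase genes 3 rose, among them Sirt2 (2.05 ± 0.34) and Sirt3 (1.55 ± 0.31), and 2 fell, with Hdac2 at -1.32 ± 0.36 (2 each when adjusted over the list alone). Of 24 bromodomain genes 3 rose, Brdt (8.82 ± 0.54 to 10.81 ± 0.09, 1.99 ± 0.41, adjusted p = 0.00225), Baz1a (1.96 ± 0.34) and Baz2b (1.12 ± 0.31), and 2 fell, with Brpf1 at -1.54 ± 0.25. Of 23 H3K4 genes 4 fell, such as Kmt2a (-1.86 ± 0.54), and 0 rose. Of 19 H3K9 and H3K36 enzyme genes 4 fell, with Setdb2 at -2.14 ± 0.39 and Ehmt1 at -1.82 ± 0.58, and 2 rose, with Kdm4d at 2.39 ± 0.56. Of 13 histone variants 3 rose, Macroh2a1 (1.75 ± 0.49), H2az1 (1.53 ± 0.34) and H2ax, and Cenpa, the centromeric histone, fell (-2.34 ± 0.61). Of 11 p53 targets 3 fell, with Gadd45a at -2.71 ± 0.48, and Zmat3 rose (1.92 ± 0.52). Kat2b was at -0.23 ± 0.39. In 6 lists of other cell types limma put 0 of 46 genes past the test, 1 of them with an unadjusted p below 0.05.

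In this comparison 3839 of 13087 genes passed, 1854 higher and 1985 lower, and 3786 did not overlap; over all genes 60.4% did not, against 20% by chance. The named changes included rises of Tmem45b (4.92 ± 0.30, adjusted p = 3.46e-07) and Fam181a (4.68 ± 0.44) and falls of Sox11 (-3.30 ± 0.47) and Gli2, developmental regulators (-3.27 ± 0.43). As lists, spermatid genes (median 1.35, adjusted camera p = 7.35e-05) and late prophase genes (1.26, 0.0130) were higher and DNA replication genes (-1.12, 0.00234) lower than other genes, with adjusted p = 0.803 with an estimated correlation. Histone acetyltransferases (median -0.94) did not pass in limma's camera test (adjusted p = 0.0519), nor did piRNA genes (0.44, adjusted p = 0.0565, but 0.0380 with the replicate number as a block) or spermatogonial genes (0.0631). Without mid-pachytene array 2 the count was 1466 and the late prophase call ended (limma's camera test, median 0.73, adjusted p = 0.0807), as it did without leptotene/zygotene array 1 (0.94, 0.0525).

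Genes on the X chromosome, which is silenced in male meiosis, lay below the autosomal level in every wild-type array, and farther below it at pachytene and diplotene. The median of 419 X-linked genes minus that of 12586 autosomal genes was -0.37 ± 0.22 in spermatogonia, -0.51 ± 0.17 in pre-leptotene and -0.73 ± 0.35 in leptotene/zygotene. It was -1.42 in early pachytene, -2.05 ± 0.47 in mid-pachytene, -3.10 in late pachytene, -3.17 ± 0.45 in diplotene and -2.53 ± 0.43 in round spermatids. The 6 pachytene and diplotene arrays lay lower than the 10 earlier ones (difference -1.97, two-sided exact permutation p = 0.000125, the smallest that 8008 splits can give), from -3.48 to -1.42 against -1.08 to -0.13. Round spermatids differed from those 6 arrays by -0.04 (exact permutation p = 0.924), and by -0.248 to 0.175 with 1 array left out. The test took no account of replicate numbers. Round spermatid arrays 1 and 2 lay above the diplotene arrays of the same number (-1.90 against -2.85 and -2.86 against -3.48). At mid-pachytene 192 X-linked genes fell (45.8%, against 14.2% of autosomal genes, Fisher's exact adjusted p = 3.88e-51) and 3 rose (0.716% against 14.6%). Among them Ids, a lysosomal sulfatase gene (-3.78 ± 0.50), Kdm6a, an H3K27 demethylase gene (-3.27 ± 0.55), Rps6ka6 (-3.21 ± 0.45) and Tex11 fell. From mid-pachytene to diplotene 174 X-linked genes fell (41.5% against 13.6%, Fisher's exact adjusted p = 4.93e-42). From diplotene to round spermatids 129 rose (30.8% against 11.8%, Fisher's exact adjusted p = 1.06e-23). At that step 0 fell, against 12.4% of autosomal genes (Fisher's exact adjusted p = 1.06e-23). The gene lists were not split by chromosome, so falls of X-linked members such as Tex11 count in them too.

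**Figure D2:**
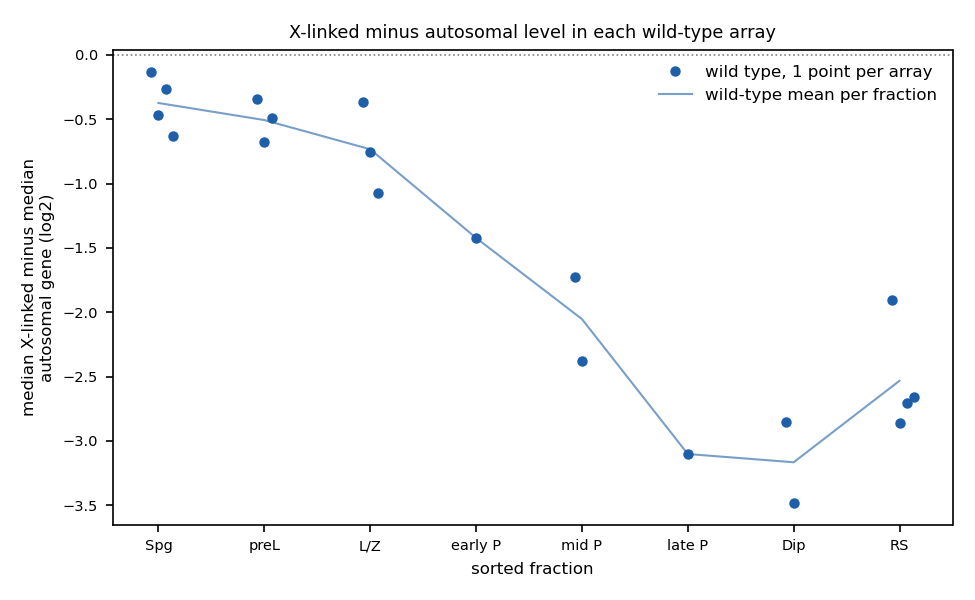
Median log2 intensity of X-linked genes minus that of autosomal genes (vertical axis) in each array, by fraction (horizontal axis). The 10 wild-type arrays up to leptotene/zygotene lay between -1.08 and -0.13 and the 6 pachytene and diplotene arrays between -3.48 and -1.42.

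From mid-pachytene to diplotene, when chromosomes begin to separate, some genes of most germ cell and chromatin lists fell. Of 25 spermatogonial genes 16 fell, 1 rose and 8 did not pass (19 fell and 1 rose when adjusted over the list alone): Zbtb16, a factor of stem cell maintenance, went from 9.56 ± 0.25 to 4.12 ± 0.45 (2 arrays each, -5.44 ± 0.89, adjusted p = 0.000515), with Lin28a at -5.20 ± 0.92, Sohlh1 at most -3.79 and Sall4 at -4.52 ± 0.90, while Dmrtb1 rose (1.33 ± 0.45). The spermatogonial list median ran from 8.19 to 9.50 in the spermatogonia arrays. It was still 9.40, 9.23 and 9.43 in leptotene/zygotene and 8.71 and 7.56 in mid-pachytene. Whether RNA of earlier germ cells contributed to the levels in those later fractions was not tested. Of 26 DNA replication genes 8 fell (9 when adjusted over the list alone). They included Mcm2 (-4.78 ± 0.72), the licensing gene Cdt1 (-4.50 ± 1.22) and Mcm4 (-4.19 ± 0.74). Of 10 meiotic entry genes Scml2 (-4.40 ± 0.51) and Stra8 (-4.02 ± 1.03) fell and Dmrtb1 rose. Of 18 strand exchange genes 7 fell and 1 rose, with Tex11 at -3.43 ± 0.75, Dmc1 at most -2.60 and Brca1 at -2.47 ± 0.42. Falls also took in Rec114 of 6 break formation genes (-3.09 ± 0.52), 3 of 13 axis genes, with Syce2 at -1.73 ± 0.43 and Sycp1 at -1.17 ± 0.37, 3 of 12 silencing genes and Mov10l1 of 17 piRNA genes (-1.80 ± 0.29). Of 19 late prophase genes 5 rose, with Pou5f2 at 2.50 ± 0.51, the kinase gene Aurkc at 1.81 ± 0.53 and Ovol1 at 1.52 ± 0.29; adjusted over the list alone 5 rose and 1 fell. Of 28 spermatid genes 1 fell, Prm2, a protamine gene (-1.52 ± 0.51; 0 when adjusted over the list alone).

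Of 21 histone acetyltransferase genes 5 fell and 1 rose between mid-pachytene and diplotene. Taf1 (-3.83 ± 0.65), Hat1 (11.37 ± 0.08 to 8.74 ± 0.05, -2.63 ± 0.33, adjusted p = 8.16e-05), Crebbp (-2.09 ± 0.34) and Ep300 (-1.12 ± 0.31) fell, and Kat5, which also acetylates repair proteins, rose (9.70 ± 0.34 to 10.93 ± 0.34, 1.23 ± 0.37, adjusted p = 0.0267). The median change of the list was -0.09 and turned to 0.24 with quantile normalization. Falls of X-linked members were not set apart in the chromatin lists. At this step 41.5% of X-linked genes fell, against 13.6% of autosomal genes. Of 23 H3K4 genes 9 fell and 0 rose (10 when adjusted over the list alone), such as the demethylase gene Kdm1b (-3.81 ± 0.74) and Kmt2a (-2.40 ± 0.59). Of 16 deacetylase genes Hdac6 (-4.34 ± 1.05) and Hdac2 (-1.73 ± 0.39) fell and Sirt4 (2.48 ± 0.57) and Sirt5 (1.57 ± 0.47) rose; of 24 bromodomain genes 4 fell and 2 rose, with Baz1b at -2.55 ± 0.37 and Smarca2 at 1.77 ± 0.58. Of 19 H3K9 and H3K36 enzyme genes 4 fell, with Ehmt1 at -3.65 ± 0.63, and of 13 histone variants Cenpa (-4.95 ± 0.67) and H2az2 (-2.17 ± 0.33) fell and H1f6 rose (at least 1.14). Of 11 p53 targets 4 fell (5 when adjusted over the list alone), with Ccng1 at -3.72 ± 0.63, and Zmat3 rose (2.28 ± 0.57). Brdt was at 0.88 ± 0.45, Kat2b at 0.01 ± 0.42 and Spo11 at 0.34 ± 0.88. Of 10 stromal markers 4 genes of smooth muscle fell beside these lists, Acta2 (-2.80 ± 0.74), Myl9 (-2.52 ± 0.83), Tagln (-2.16 ± 0.74) and Myh11 (-1.66 ± 0.56), and 1 fell with either scaling; limma put 0 of 36 markers in the other 5 lists past the test, and 0 had an unadjusted p below 0.05.

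In all, 2812 of 13087 genes passed, 913 higher and 1899 lower, and 2810 did not overlap; over all genes 60.2% did not, against 33.3% by chance. The named rises included Thsd7b (3.97 ± 0.52), the channel gene Trpv1 (at least 2.63), the growth factor gene Gdf9 (3.52 ± 0.43) and Prdm8 (at least 2.87). Spermatogonial genes (median -3.25, adjusted camera p = 2.65e-08) and H3K4 genes (-0.58, 0.0185) were lower and late prophase genes (0.81, 0.0107) higher than other genes, with adjusted p = 0.803 with an estimated correlation. DNA replication genes (-0.33) did not pass in limma's camera test (adjusted p = 0.0519, but 0.0441 with the replicate number as a block). The late prophase call ended without mid-pachytene array 1 (limma's camera test, median 0.59, adjusted p = 0.0813) and without diplotene array 2 (0.43, 0.107). Quantile normalization gave 1247 higher and 1584 lower (44.0% higher, against 32.5%) and median centring 1631 and 1526 (51.7%), with the median of all genes at 0.13 and 0.30. A limma fit on the arrays of these 2 fractions alone gave 0 genes, with 4023 at an unadjusted p below 0.05, and the count was 1339 without mid-pachytene array 1 and 1417 without diplotene array 2.

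From diplotene to round spermatids, the haploid cells, 16 of 28 spermatid genes rose and 8 of 17 piRNA genes fell. Of 28 spermatid genes 16 rose and 12 did not pass, and 20 rose when adjusted over the list alone. Akap4 went from 10.07 ± 0.01 in 2 arrays to 12.55 ± 0.32 in 4 (2.48 ± 0.63, adjusted p = 0.00797), with the sperm channel gene Catsper3 at 2.86 ± 0.67, the egg-binding gene Izumo1 at 2.58 ± 0.64 and Tssk3 at 2.49 ± 0.67. Of 17 piRNA genes 8 fell, among them Tdrd5 (-2.65 ± 0.43), Piwil1 (-2.09 ± 0.33), Pld6 (-1.49 ± 0.29) and Piwil2 (-1.43 ± 0.35). Of 18 strand exchange genes 4 fell, with Ccnb1ip1, a regulator of crossing over, at -3.86 ± 0.22 (adjusted p = 4.44e-08), and 2 rose, Tex15 (1.82 ± 0.26) and Brca1 (1.47 ± 0.36); 5 fell when adjusted over the list alone. Of 13 axis genes 3 fell, such as Tex12 (-2.90 ± 0.44) and Sycp2 (-1.51 ± 0.33), and the meiotic cohesin gene Rec8 rose (2.83 ± 0.45). Of 26 replication genes 5 fell, with Ccne2 at -3.29 ± 0.51, and Rrm2 rose (1.86 ± 0.32). Of 12 silencing genes 4 fell and 2 rose, with Topbp1 at -2.34 ± 0.34 (5 fell when adjusted over the list alone). Of 19 late prophase genes 2 rose, with Cdc25c at 2.11 ± 0.32, and 2 fell, with Pou5f2 at -2.13 ± 0.44. Of 10 meiotic entry genes Rec8 and Scml2 (1.28 ± 0.44) rose and Tex101 fell (-3.42 ± 0.75; 3 fell when adjusted over the list alone), and of 25 spermatogonial genes Id4 (-2.31 ± 0.61) and Dnmt3b (-2.02 ± 0.61) fell (1 when adjusted over the list alone). Of 11 p53 targets Mdm2 rose (1.55 ± 0.43) and Trp53inp1 fell (-1.43 ± 0.43); in the break formation list limma put 0 of 6 genes past the test and 1 had an unadjusted p below 0.05, with Spo11 at -1.39 ± 0.76.

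Histone acetylation genes went both ways in round spermatids, as all genes did, with 1633 of 13087 higher and 1566 lower. Neither acetyltransferases nor deacetylases passed as lists in limma's camera test (adjusted p = 0.808 and 0.687). Of 21 acetyltransferase genes 3 rose, Cdyl (2.24 ± 0.37), Kat2b (7.32 ± 0.15 to 9.54 ± 0.09, 2.22 ± 0.37, adjusted p = 0.000385) and Hat1 (1.10 ± 0.29), and 4 fell, with Clock at -2.34 ± 0.43 and Kat6a at -2.32 ± 0.37. Of 16 deacetylase genes Hdac11 (3.10 ± 0.60) and Hdac5 (2.32 ± 0.49) rose and 3 fell, with Sirt7 at -3.51 ± 0.68 and Sirt1 at -1.80 ± 0.30. Of 24 bromodomain genes 5 fell and 2 rose, with Phip at -2.30 ± 0.51 and Baz1a at -2.19 ± 0.32. Of 23 H3K4 genes 4 fell and 2 rose, with Kmt2d at -2.67 ± 0.33, and of 19 H3K9 and H3K36 enzyme genes 3 fell and Suv39h2 rose (2.18 ± 0.32). The spermatid linker histone gene H1f7 was the 1 of 13 histone variants that rose (2.20 ± 0.67; 0 when adjusted over the list alone). Crebbp was at 0.67 ± 0.29, Ep300 at 0.31 ± 0.27 and Brdt at 0.07 ± 0.39. Beside these genes, 3 of 10 stromal markers rose (4 when adjusted over the list alone), Dcn (3.94 ± 1.16), Col1a2 (at least 2.61) and Col3a1 (2.40 ± 0.80), and 1 of 12 leukocyte markers, Adgre1 (at least 0.72; 0 when adjusted over the list alone). In the 4 other lists limma put 0 of 24 markers past the test, and 0 had an unadjusted p below 0.05.

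**Figure D3:**
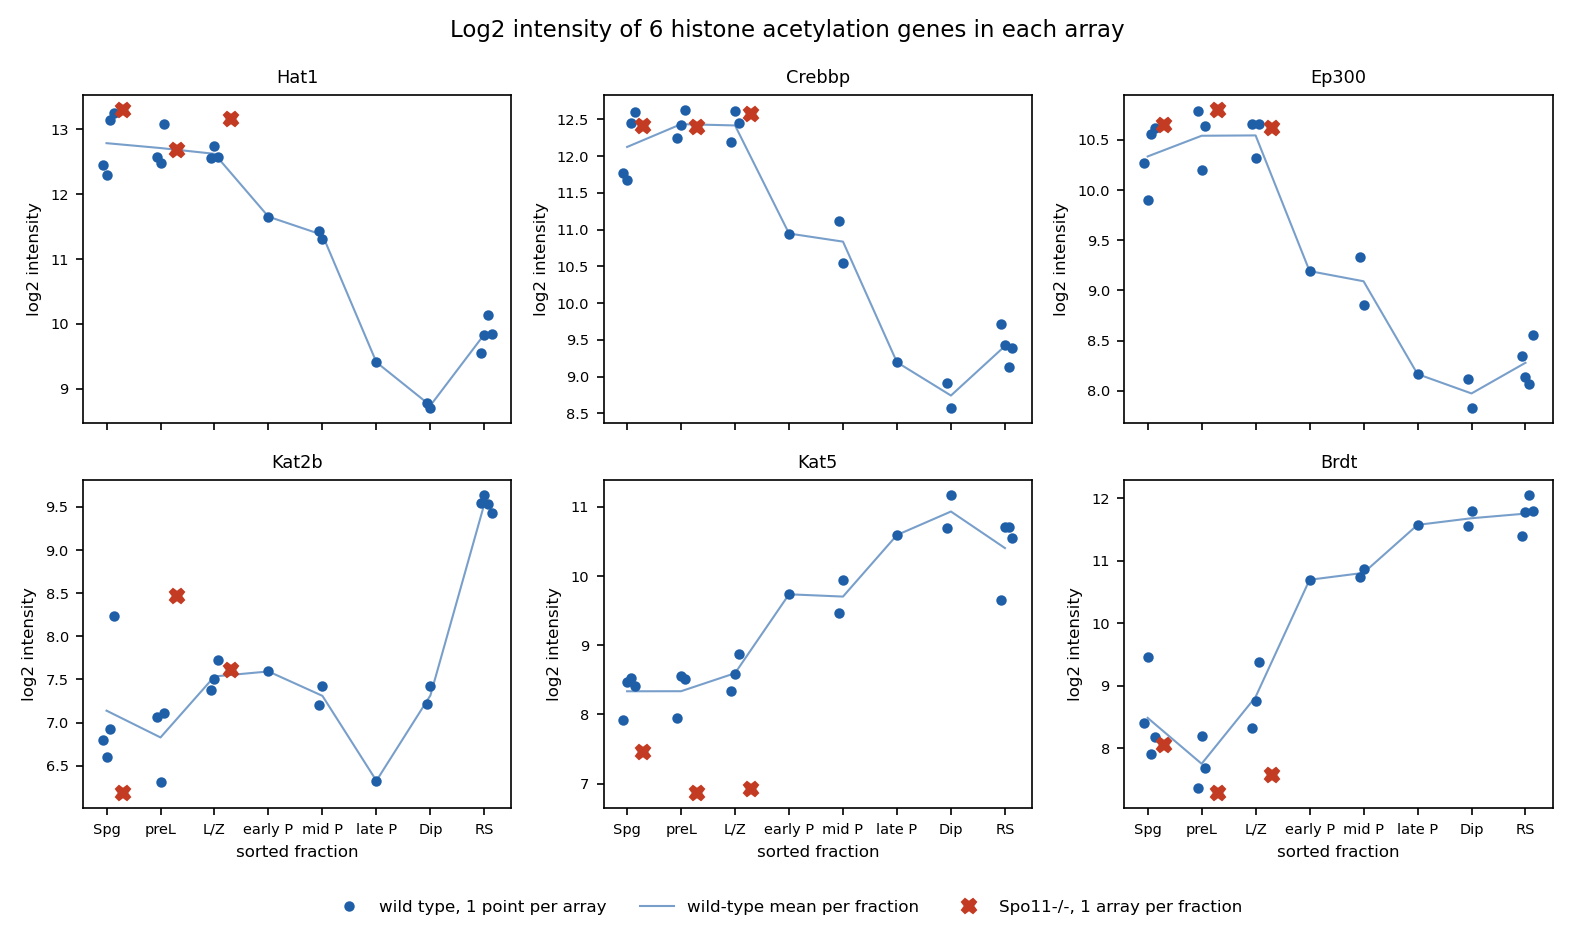
Log2 intensity (vertical axis) of Hat1, Crebbp, Ep300, Kat2b, Kat5 and Brdt in each array, by fraction (horizontal axis); points are wild-type arrays, the line joins their means, and red crosses are the Spo11-/- arrays. Crebbp fell from 12.42 in leptotene/zygotene to 10.84 in mid-pachytene and 8.74 in diplotene, and Kat2b rose from 7.32 in diplotene to 9.54 in round spermatids.

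In all, 3199 of 13087 genes passed, 1633 higher and 1566 lower; 2996 did not overlap, and over all genes 42.9% did not, against 13.3% by chance. The named rises included Dct, a pigment enzyme gene (2.31 ± 0.08 to 7.08 ± 0.54, at least 3.08, adjusted p = 4.44e-08), Limch1 (at least 3.27) and Nkx2-6 (3.80 ± 0.52), and the named falls included Exosc7 (-4.35 ± 0.47), Tm2d3 (-4.32 ± 0.47) and the Polycomb gene Rnf2 (-3.71 ± 0.55). Spermatid genes were higher than other genes as a list (median 2.09, adjusted camera p = 3.73e-06), with adjusted p = 0.803 with an estimated correlation; piRNA genes (-0.88) had an adjusted camera p of 0.0519, and of 0.0336 with the replicate number as a block. Without diplotene array 1 the count was 1691.

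Spo11-/- and wild-type cells of the 3 early fractions were compared with the fraction as a term. Spo11 itself was lower, at 4.77 ± 0.46 in 3 Spo11-/- arrays and 6.67 ± 1.48 in 10 wild-type arrays (-1.97 ± 0.59, adjusted p = 0.0408); the values were 4.30, 4.81 and 5.21, while wild-type spermatogonia array 1 was at 4.60. The call ended in 9 of 13 fits that left out 1 array and in 7 of 13 other settings, and whether the probe set lies in the deleted part is not stated. Genes of spermatids fell together: of 28, 25 fell (28 when adjusted over the list alone). For genes higher in a later wild-type fraction, RNA of later germ cells in the early wild-type arrays is a candidate source, weighed below. Prm1 and Prm2, the protamines that pack sperm DNA, fell by at least 10.20 and 9.45, with Prm1 at 3.27 ± 0.09 against 14.20 ± 0.69 (adjusted p = 4.89e-09), and Tnp1 (at most -8.97), Tnp2 (at most -8.48) and Smcp (at most -8.26) fell too. Outside the lists, Gsg1 fell as well (at most -7.45). Of 18 late prophase genes 8 fell, with Ldhc at most -8.07, Pgk2 at most -6.70, Adam2 at most -4.58 and Ccna1 at -3.07 ± 0.60. Of 12 histone variants H1f7 (-7.34 ± 0.60), H2bl1 (at most -5.31) and H2al2a (at most -5.18), all of spermatids, fell, and of 17 piRNA genes Piwil1 (-2.53 ± 0.34), Gtsf1 (-1.54 ± 0.34) and Pld6 (-1.05 ± 0.20). Of 25 spermatogonial genes 7 fell, with Lin28a at -3.31 ± 0.66, Gfra1, a receptor of stem cells, at -2.48 ± 0.39, Id4 at -2.39 ± 0.45 and Ddit4 at -2.27 ± 0.42.

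Few genes of chromatin or recombination passed between Spo11-/- and wild type. Kat5 was the 1 of 21 acetyltransferase genes that fell (7.08 ± 0.32 against 8.41 ± 0.29, -1.33 ± 0.22, adjusted p = 0.00188), with Hdac11 (-1.35 ± 0.18) and Hdac5 (-1.22 ± 0.33) of 16 deacetylase genes and Brd1 of 24 bromodomain genes (-1.30 ± 0.34; 0 when adjusted over the list alone). Of 19 H3K9 and H3K36 enzyme genes Kdm4d fell (-2.52 ± 0.61) and Kdm4c rose (1.39 ± 0.30). In wild type, Kat5 rose at diplotene, Hdac11 and Hdac5 in round spermatids, and Kdm4d at leptotene/zygotene and mid-pachytene. Whether RNA of later germ cells in the wild-type arrays contributed to these differences was not tested gene by gene. Spo11 was the 1 of 6 break formation genes that fell, 1 of 18 strand exchange genes fell, Ythdc2 rose among 10 meiotic entry genes (1.13 ± 0.34) and Ccne2 among 26 replication genes (1.19 ± 0.32; 0 when adjusted over the list alone). Of 12 p53 targets Sesn2 fell (-1.87 ± 0.40) and Plk3 rose (at least 0.29). In the axis, silencing and H3K4 lists limma put 0 of 46 genes past the test, and 12 had an unadjusted p below 0.05. Changes were 0.35 ± 0.23 for Hat1, 0.14 ± 0.21 for Crebbp, 0.22 ± 0.19 for Ep300, -0.19 ± 0.26 for Brdt, 0.63 ± 0.28 for Dmc1 and 0.92 ± 0.35 for Prdm9. Beside these genes, Leydig cell markers Cyp17a1 (at most -1.69) and Ptgds (-2.55 ± 0.59), 3 of 10 stromal markers, with Acta2 at -2.36 ± 0.67, and the endothelial marker Egfl7 (-1.25 ± 0.19; 3 of 6 when adjusted over the list alone) fell. Of 10 Sertoli cell markers 1 rose, Aard (1.42 ± 0.31; 2 when adjusted over the list alone), and 5 did so with quantile normalization and 4 with median centring. Of 12 leukocyte markers limma put 0 past the test (0 with an unadjusted p below 0.05). Red blood cell markers were not tested as a list in any comparison, and Slc4a1 and Hba-a2 lay at 3.85 and 3.10 in wild-type pre-leptotene cells.

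The named rises in Spo11-/- were those of the cytokine gene Tnfsf11 (at least 2.40), the lymphocyte genes Cd69 (at least 2.12) and Il17a (at least 1.67), Mid1 (8.70 ± 0.24 against 5.98 ± 0.69, 2.72 ± 0.36, adjusted p = 0.000489), Iqgap2 (2.58 ± 0.49), Psg28 (2.18 ± 0.59), Gstm6 (2.17 ± 0.32) and Nt5e (2.14 ± 0.49). Without the Spo11-/- pre-leptotene array the calls of Tnfsf11, Cd69 and Il17a ended. They lay at 5.16, 4.64 and 4.22 in the Spo11-/- spermatogonia array and at 2.80, 2.95 and 3.50 in the leptotene/zygotene array. In the Spo11-/- pre-leptotene array the leukocyte markers had a median of 6.07, with Ptprc at 12.91, and the stromal markers one of 7.64, against leukocyte medians of 2.78 and 2.70 in the Spo11-/- spermatogonia and leptotene/zygotene arrays. The wild-type pre-leptotene arrays had leukocyte medians of 5.97, 2.69 and 2.83 and stromal medians of 5.79, 5.01 and 4.20, and the wild-type spermatogonia arrays had leukocyte medians from 4.44 to 7.57. Counted without a test, 427 genes in the Spo11-/- pre-leptotene array lay at least log2 2 above, and 375 below, every wild-type array of the fraction. In spermatogonia 4 lay above and 568 below, and in leptotene/zygotene 14 and 696. A wild-type array set against the others of its fraction in this way gave from 0 to 165 genes above and from 2 to 40 below.

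In all, 1386 of 12015 genes passed between Spo11-/- and wild type, 203 higher and 1183 lower; 1270 had every Spo11-/- array beyond the wild-type arrays of its own fraction, and over all genes 21.9% did, against 2.5% by chance. Of the 1183 lower genes, 673 (56.9%) had their highest wild-type mean in round spermatids, against 18.1% of 10520 genes that did not pass, and 251 were not higher in any later fraction. Spermatid genes (median -4.88, or -3.93 with genes below log2 4 at their bounds, adjusted camera p = 1.64e-23), late prophase genes (-0.70, 0.00747) and spermatogonial genes (-0.56, or -0.41, 0.0156) were lower and Sertoli cell markers (0.78, 0.00234) higher than other genes, with adjusted p = 0.803 with an estimated correlation. Without the Spo11-/- pre-leptotene array the late prophase (limma's camera test, median -0.84, adjusted p = 0.0659), spermatogonial (-0.33, 0.105) and Sertoli (0.39, 0.105) calls ended. Over 13 fits without 1 array the medians ran from -1.14 to -0.38 (late prophase), -0.65 to -0.33 (spermatogonial) and 0.39 to 1.11 (Sertoli). Quantile normalization gave 685 higher and 785 lower (46.6% higher, against 14.6%) and median centring 468 and 982 (32.3%), with the median of all genes at 0.16 and 0.17; 340 genes passed among those not higher in a later fraction (117 higher, 223 lower), and 836 without the Spo11-/- leptotene/zygotene array. The labels give neither the strain of the Spo11-/- mice nor the occasions of collection, and a difference in either could not be told apart from genotype.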

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

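Chosen after the results were seen were the tests of scaling and of other choices of arrays for Spo11-/-, of another tissue, of the 251 genes in 2 parts, and of splits refitted on the arrays of 2 fractions alone; the T cell and B cell lists were written after the first genes high in the Spo11-/- pre-leptotene array were seen, and left those out.

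For the genes lower in Spo11-/-, scaling of the arrays as the whole cause is argued against, since 66.1% of the genes called lower (782) were also called lower under quantile normalization. Chance as the whole cause is argued against too, if the 3 Spo11-/- arrays are taken as independent, although they may share mice. Of the 80 ways to pick 1 array per fraction, 1 gave as many genes, the real one with 1386. The highest other, the wild-type arrays numbered 1, gave 127. RNA of later germ cells in the early wild-type fractions is a candidate source for the 932 genes higher in a later fraction. Of 1226 genes at least log2 5 higher in round spermatids than in Spo11-/-, 80.02% lay at least log2 1 higher in early wild-type arrays. This is just past the 80% set beforehand, and choosing genes by their low Spo11-/- level favours it. The median share of the round spermatid level needed was 0.0253 (quartiles 0.0137 and 0.0524). Early wild-type levels were far higher for some genes, at 14.20 for Prm1 and 12.48 for Tnp2. The spermatid list median was 11.97 in spermatogonia array 2, against 12.15 to 12.70 in round spermatids. A single share therefore does not hold for all of these genes. The Hoechst sort is the gate meant to remove later germ cells. For the 251 genes not higher later the median share of the highest later fraction would have to be 0.8347, between the bounds. For the 187 of them with that level in pachytene or diplotene the median share needed was 0.9839. It is high by their selection and decides nothing by itself. The abundant genes of these fractions, chosen whatever their early wild-type level, showed far lower shares, with upper quartiles of at most 0.198. If cells bring all their RNA in a common share, that argues against the measured pachytene and diplotene cells as the source for the 187. A common share did not hold for the genes of round spermatids above, which limits this argument. Later spermatids were not measured and are not covered by it. The other 64 needed 0.4937 of the round spermatid level but changed by -2.66 from spermatogonia to pre-leptotene, as the 1226 genes did (-1.09), and later spermatids were not measured, so this source cannot be told apart from others; loss of Spo11 as the biological cause, mouse strain and the occasion of collection were not tested.

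For 256 of 12015 genes limma's F test of the interaction put the difference between Spo11-/- and wild type apart between the 3 fractions (1337 at an unadjusted p below 0.05; 238 stood farthest apart in pre-leptotene), but each fraction had 1 Spo11-/- array and the spread came from wild type alone, so a single array's own deviation cannot be told apart from a difference between fractions. An array of another tissue under this label is argued against by the median of the 13 axis genes, 0.02611 log2 from the wild-type pre-leptotene mean. T cells in the sorted pool are a candidate source: 88.24% of 17 measured T cell markers lay at least log2 2 above every wild-type pre-leptotene array, with Cd3g at 11.42, Thy1 at 11.83 and Il7r at 10.87 against at most 2.58, 2.89 and 2.79 in those arrays, while 4 of the 17 reached log2 4 in a wild-type pre-leptotene array and 0 were in another list. B cells stay open, with 25% of 4 markers above. Whether the Hoechst sort would remove T or B cells was not tested, and no biological explanation was tested.

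Of 28 spermatid, 10 stromal and 12 leukocyte genes 7, 3 and 2 were lower in pre-leptotene than in spermatogonia, and limma's list calls were lost (adjusted p = 0.803 with an estimated correlation); no explanation was tested for the stromal and leukocyte genes. RNA of later germ cells in the spermatogonia arrays is a candidate source for the spermatid genes. Of the 1226 genes above, 94.05% were lower in pre-leptotene (median -1.09), counted at any size of fall. Any cause that lowers genes of round spermatids together would give this too, so it does not decide for this source. The real split of the 7 arrays gave 223 genes, and 2 of 35 splits gave as many, so chance cannot be excluded. The highest other, spermatogonia arrays 1, 2 and 3 against the rest, gave 555 and points to a structure of the samples. That split parts 3 pairs of replicate numbers, as the real one does, and the blocked fit gave 625. Refitted on these arrays alone the real split gave 0 and the highest other 2, so that 35 of 35 giving as many was fixed beforehand and decides nothing. For leptotene/zygotene against pre-leptotene 10 splits are too few for a share under 0.05: the real split gave 407 and the highest other 1, so 1 split gave as many, and 0 and 0 when refitted on these arrays alone, where all 10 had to.

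The H3K9 and H3K36 enzyme genes had a median of 7.724 in round spermatid array 1, away from 8.046 to 8.112 in the other 3 arrays. It was the only array that the rule picked out among the 66 groups of values looked at. Chance picks out about 1 in 20 groups (5.02% of simulated groups of 4 normal values). Other arrays stood apart without being picked out, such as wild-type pre-leptotene array 1 in the leukocyte median (5.97 against 2.69 and 2.83).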

How the results depend on the processing

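Alternatives chosen after the data were seen were the restriction to genes not higher in a later fraction, the fit without markers of other cell types, the fit without spermatogonia arrays 1 and 2, and the list tests without each array. No named gene past the test changed direction under any setting. For pre-leptotene against spermatogonia (223 genes), no filter gave 10, the mean over probe sets 99, each probe set on its own 54, quantile normalization 27, median centring 37, array weights 830, the replicate block 625, genes not higher later 37, dropping spermatogonia arrays 1 and 2 gave 39, and a fit on the arrays of the 2 fractions 0 (limma, 1222 at an unadjusted p below 0.05). Leaving out 1 array gave 8 to 596: 23, 56, 428 and 596 without spermatogonia arrays 1 to 4, 38 and 8 without pre-leptotene arrays 1 and 3. For leptotene/zygotene against pre-leptotene (407), no filter gave 164, quantile normalization 232, median centring 196, array weights 748, a fold minimum of log2 2 gave 261, the block 630, the 2 fractions alone 0 (limma, 2021 unadjusted) and genes not higher later 0 (282 unadjusted). Leaving out 1 array gave 25 to 623: 25 and 64 without pre-leptotene arrays 1 and 3, 623, 248 and 33 without leptotene/zygotene arrays 1, 2 and 3. For mid-pachytene (3839) the larger fold minimum gave 1273, and leaving out 1 array 1466 (mid-pachytene 2) to 3818. For diplotene (2812) it gave 1349, the 2 fractions alone 0 (limma, 4023 unadjusted), and leaving out 1 array 1339 (mid-pachytene 1) to 2579, with 1417 without diplotene 2. For round spermatids (3199) each probe set on its own gave 4820, the larger fold minimum 1354, and leaving out 1 array 1691 (diplotene 1) to 3236. For Spo11-/- (1386) the larger fold minimum gave 750, genes not higher later 340, and leaving out 1 array 836 (the Spo11-/- leptotene/zygotene array) to 1476; the lone array left in a group was assumed to vary like the others. With the spread from wild type alone, single fractions gave 468 (spermatogonia; 39 higher, 429 lower), 964 (pre-leptotene; 528 higher, 436 lower) and 397 (leptotene/zygotene; 31 higher, 366 lower); with 1 Spo11-/- array each, these cannot tell genotype from that array's own deviation. Within single fractions, a difference of log2 1 gave 1182, 2040 and 1532 genes in place of 572, 802 and 710. Of 132 list tests 22 passed in camera, 30 in fry and 0 in camera with an estimated correlation (7 unadjusted); leaving out 1 array from every comparison that held it gave 20 to 27 in camera. Fewer genes tested, fewer arrays or a larger minimum account by construction for part of these changes; for the filter, the probe set choice, the scalings, the weights, the block and the correlation the cause was not tested. The block moved the camera calls of piRNA genes past the threshold at pre-leptotene (0.0343 against 0.145), mid-pachytene (0.0380 against 0.0565) and round spermatids (0.0336 against 0.0519), and of replication genes at diplotene (0.0441 against 0.0519), and of no other list. The X-linked difference of -1.97 ran from -2.27 to -1.14 over all settings, each past the threshold. Between 44.2% and 47.3% of probe sets per array reached log2 4, which limits what can be seen below it.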

Other observations

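Early and late pachytene had 1 array each, and their values were not tested. The early pachytene array held Hat1 at 11.65 and Spo11 at 10.02, and the late pachytene array held them at 9.41 and 11.27. Medians of gene lists were lower in the late than in the early array for DNA replication genes (8.37 and 10.19), spermatogonial genes (6.08 and 8.34) and p53 targets (5.68 and 6.80). The histone acetyltransferases had medians of 8.73 in the early and 9.05 in the late array, and the late prophase genes 11.10 and 10.94. Spermatid genes, which serve the shaping of sperm, had a median of 10.89 in the early array and 8.94 in the late array. Kat2b, an acetyltransferase gene, was at 6.33 in the late array.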
